A study of Homo sapiens with 3 samples.

How the data were processed

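Polyadenylated RNA was measured in HEK293T cells, a human embryonic kidney cell line that is easily transfected. Per the labels' protocols, siRNAs were introduced by reverse transfection with a lipid reagent, in which cells are seeded onto the siRNA mixture, and the cells were harvested 48 h after seeding without TGF-beta. There were 3 libraries: 1 with a negative control siRNA, 1 with an siRNA against ESRP2 and 1 with an siRNA against Arkadia, the protein encoded by RNF111. Libraries were made with an Ion Total RNA-seq kit and read on an Ion semiconductor sequencer, per the labels' protocols.

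The deposited FPKM values (fragment numbers scaled to transcript length and library size) were made by the authors with TopHat2 2.0.10, Bowtie2 2.1.0, Cufflinks 2.1.1 and Cuffdiff on the build hg19, per the submitters' processing notes. Their order, the Cuffdiff version, its scaling between libraries, its dispersion model and any use of strand are not given in the sources used here. A gene table gave 23284 genes and an isoform table gave 41138 RefSeq isoforms, each with the authors' FPKM, a lower and an upper confidence bound and a quantification status per library, per the file headers. Gene positions are those of the deposited tables on hg19, given here from 1; a locus can span neighbouring genes that Cuffdiff quantified together. The status was OK for 23186 genes. The FPKM lay outside its own interval for 39 to 43 genes and 997 to 1064 isoforms per library, mostly near 0, so intervals are used as the authors gave them and not as exact limits.

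No counts were used here. The interval bounds of low genes longer than 1000 nt and with FPKM up to 0.6 were whole multiples of a unit (tolerance 0.01) for 1979 of 3820 genes examined, the unit was the same to within 1% for 81.9% of these 1979 genes, and on this unit 1 read was worth 1.00 in the control library, 0.968 in the ESRP2 siRNA library and 1.34 in the Arkadia siRNA library. This implied about 11.9, 12.3 and 8.90 M reads. The Arkadia siRNA library was thus the shallowest, and 1 read on a 1 kb transcript corresponded to an FPKM of 0.0840, 0.0812 and 0.112. Approximate reads given below come from these values and are estimates.

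From the deposited FPKM, log2((FPKM + 1)/(FPKM + 1)) was computed per gene and comparison; on this scale the changes of low genes are understated. Linear FPKM ratios are given beside it where FPKM is above 0. Genes entered with a mean FPKM of at least 1 over the 3 libraries, status OK in each library and a longest isoform of at least 300 nt, which left 11870 genes. Each group has 1 library, so there are no replicates, no tests and no p-values: the comparisons are between libraries and not between conditions. A gene is said to have risen or fallen when it passed the fixed size of 2-fold; for the members of the fixed gene lists the size was 1.5-fold. Whether the authors' intervals of the libraries overlapped is given beside it.

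As a measure of the noise the intervals imply, 100 sets of unchanged libraries were drawn around the mean of the 3 libraries, with an SD set from the width of each interval, taken as 4 SD, and counted in the same way. For each of 23 fixed gene lists the members higher, lower and neither were counted, and the median was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins, as a description of these libraries. Isoform usage was computed for genes with at least 2 isoforms and a summed FPKM of at least 5 in each library, as the share of each isoform in the gene's summed FPKM; a usage change is the summed absolute change of shares divided by 2, and 0.25 was the threshold.

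Named genes were chosen by rule. They are the siRNA targets and ESRP1; the 12 largest rises and 12 largest falls per knockdown among genes with FPKM of at least 5 in the higher library and intervals that did not overlap; the 8 largest rises and falls shared by both knockdowns; up to 5 each way in the direct comparison; up to 4 members per list; the 8 genes with the largest usage change per knockdown; and the ESRP splicing targets that entered the isoform comparison. The groups, the comparisons, the thresholds, the lists, this rule and the alternatives for pseudocount, filter, scaling, status, gene or isoform table and intervals were fixed before the data were examined.

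Chosen after the data were seen were the subtraction of decile medians over transcript GC content and over transcript length, the matching of random lists on isoform number, the split of ribosomal protein genes by annotated pseudogenes, the split of isoform results by summed FPKM, the comparison with other short genes and the lengths of isoform pairs. Transcript length was that of the gene's longest isoform. GC content came from GENCODE 29 transcripts matched by RefSeq accession for 97.2% of genes and by symbol for 1.83%. That annotation is on a later build than hg19, so no coordinates were taken from it. Results for some single genes are not reported here, although counts and list medians include them.

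The computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with Poisson reads at the implied depths. For ESRP2 siRNA against control siRNA, with 11870 genes, 100% of 100 genes changed 4-fold and 100% of 100 genes changed 3-fold passed the 2-fold size in the right direction. Of the 11670 other genes, 0.00857% passed it. The changed genes were drawn from those with a mean FPKM of at least 5, so their recovery does not cover lower genes. Poisson reads leave out the variation between cultures and library preparations.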

Results

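Transcript levels were compared between HEK293T cells that received an siRNA against ESRP2, an siRNA against Arkadia (encoded by RNF111) or a negative control siRNA, with 1 library each. Arkadia is a RING-type ubiquitin ligase known from TGF-beta signalling, and ESRP2 is an epithelial splicing regulator. The design asks which transcripts follow the loss of each protein and whether both losses act on the same ones. There are no replicates, so each difference below is a difference between 2 libraries. The implied depth was about 11.9 M reads for control siRNA, 12.3 M for ESRP2 siRNA and 8.90 M for Arkadia siRNA. Of 23284 genes, 11879, 11814 and 11837 had an FPKM of 1 or more in these libraries. Across the 11870 genes compared, log2(FPKM + 1) correlated with Pearson's r of 0.954 between ESRP2 and control siRNA, 0.968 between Arkadia and control siRNA and 0.907 between both knockdowns, where genes are not independent replicates. RPS18 was the most abundant gene in each library, and ribosomal proteins made up 28%, 25.1% and 29.9% of summed FPKM in the control, ESRP2 and Arkadia siRNA libraries.

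Each targeted transcript was lower in the library that received its siRNA. RNF111 (chromosome 15, 59279865 to 59389253 on hg19) had an FPKM of 6.38 with control siRNA, with an authors' interval of 3.15 to 9.59, and 1.15 (0.50 to 1.82) with Arkadia siRNA. This was 81.9% lower, a log2 ratio of -1.78, from about 420 reads to about 57, and the intervals did not overlap. With ESRP2 siRNA it was 7.65 (3.79 to 11.5). ESRP2, whose locus in the table spans chromosome 16, 68119269 to 68270136 and so covers neighbouring genes, had an FPKM of 14.8 (3.34 to 26.3) with control siRNA and 4.27 (0.0878 to 9.33) with ESRP2 siRNA. It was 71.1% lower with a log2 ratio of -1.58, while the intervals overlapped. With Arkadia siRNA ESRP2 was 21.2 (6.21 to 36.5), an overlapping interval again, so a fall of the ESRP2 transcript after Arkadia siRNA was not seen. ESRP1, the paralog of ESRP2, was near the floor, at 0.116 and 0.123 with control and Arkadia siRNA, and was listed at 0 with ESRP2 siRNA.

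**Figure D1:**
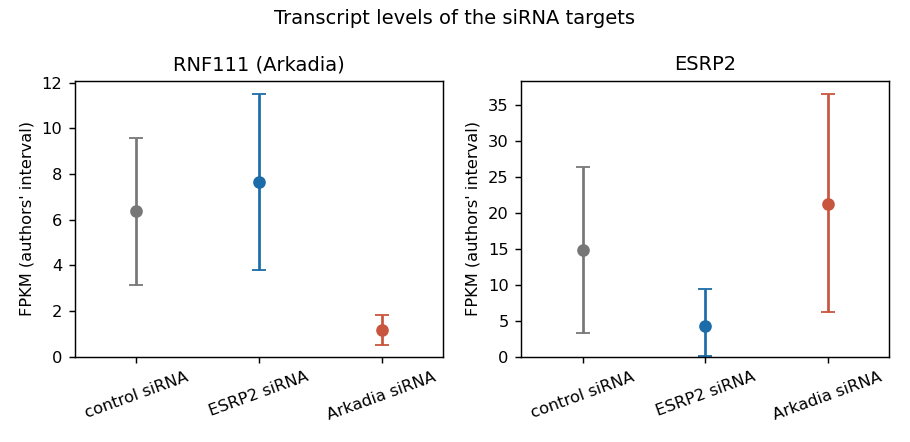
FPKM of RNF111 (left) and ESRP2 (right) in the control, ESRP2 and Arkadia siRNA libraries; points are the deposited FPKM of 1 library each and bars the authors' confidence intervals. RNF111 was 1.15 with Arkadia siRNA against 6.38 with control siRNA, and ESRP2 was 4.27 with ESRP2 siRNA against 14.8.

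With ESRP2 siRNA, the rises of genes with an FPKM of at least 5 in the higher library and intervals that did not overlap were led by TMEM126A, a mitochondrial inner membrane protein, which went from an FPKM of 22.8 (9.90 to 35.7) to 429 (204 to 654), an 18.8-fold difference. ARL6IP1, a protein that shapes the endoplasmic reticulum, rose from 26.0 to 191, the ribosome assembly factor FCF1 from 7.33 to 52.3, and the endosomal sorting protein SNX3 from 55.4 to 304. RHEB, the GTPase that activates mTORC1, rose 4.86-fold and the actin-capping subunit CAPZB 4.56-fold from 172 to 785. Falls of such genes were led by SDF2L1, an endoplasmic reticulum stress gene, from 177 (82.2 to 271) to 37.4 (16.9 to 57.8), the synaptic vesicle protein SYP from 31.2 to 6.51 and the G protein subunit GNB2 from 169 to 39.1. BID, a BH3-only apoptosis gene, fell from 25.3 to 5.63, the copper chaperone CCS from 43.4 to 11.7 and the protease inhibitor CSTB from 212 to 60.9.

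Among the other large rises of this kind, DNTTIP2 changed by a log2 ratio of 2.53, FAM49B by 2.43, PHTF2 by 2.39, LIX1L by 2.17 and the homeodomain factor CUX1 by 2.11. TMEM184B fell by 2.08 on this scale, SLC10A3 by 2.04, RPS28 by 1.91 and the neuronal adaptor subunit AP3B2 by 1.90; RAB11B and CTXN1 completed the 12 falls, the latter with 1.78. Larger ratios of genes whose intervals overlapped, such as BSCL2, are left out here.

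In total, 647 of 11870 genes rose and 287 fell at least 2-fold with ESRP2 siRNA, and 102 and 46 of them had intervals that did not overlap. Unchanged libraries drawn from the authors' intervals gave a total of 954 such genes (885 to 1023 over 100 sets), so the total of 934 was not larger than the noise those intervals imply. The median log2 ratio of all genes was 0.12; rescaling by the median of ratios moved it by -0.11 and gave 417 higher and 448 lower genes, and rescaling to the upper quartile gave 361 and 522. The log2 ratio fell with transcript GC content, with a Spearman correlation of -0.64 across genes and a decile median of 0.61 at a GC content of 37.4% against -0.49 at 64.4%. After the decile medians were subtracted 274 genes were higher and 183 lower.

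At 1.5-fold, the size used for the lists, 2361 of all 11870 genes rose and 1354 fell with ESRP2 siRNA. Ribosomal protein genes were lower as a group with ESRP2 siRNA. Of 77 measured, 12 rose, 17 fell and 48 did neither at 1.5-fold; the median log2 ratio was -0.24, lower than in each of 10000 matched random lists, and -0.35 after GC subtraction. RPS28 fell from 821 to 218, whereas RPS27A rose from 548 to 1950 and RPL27 from 1825 to 5317; reads of these genes can be shared with processed pseudogenes. Replication-dependent histones had 3 rises and 10 falls among 23, with a median of -0.31 (percentile 0.375, and 3.99 after GC subtraction); their transcripts largely lack poly(A) tails, the copies resemble each other, and HIST1H1D was listed at 0 with ESRP2 siRNA against 2.42 with control siRNA. Genes of the unfolded protein and amino acid stress response had 2 rises and 8 falls among 28, with a median of -0.16 (percentile 1.99, and 0.0600 after GC subtraction). DDIT4 fell from 67.4 to 25.8 beside SDF2L1, and the chaperone HSP90B1 rose from 238 to 407.

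Mitosis genes were higher, with 8 rises and 1 fall among 30 and a median of 0.40 at percentile 97.6. CDK1 rose from 69.7 to 181 and CCNA2 from 54.6 to 113, and AURKB fell from 169 to 107. This list followed the GC trend and had a median of 0.03 at percentile 41.8 after GC subtraction. Splicing regulators had 6 rises and 7 falls among 39, with a median of 0.10 at percentile 38.8. After GC subtraction their median was -0.35, lower than in all random lists. The 7 falls included ESRP2 itself, the target of the siRNA. PTBP2 rose from 7.02 to 18.0 and MBNL1 from 8.18 to 20.4, and U2AF2 fell from 195 to 84.4.

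The lists closest to the known roles of Arkadia and ESRP2 stayed inside the central 95% of random lists. TGF-beta and BMP pathway components had 4 rises and 3 falls among 29; the inhibitory SMAD6 fell from 5.99 to 1.35, and USP15, a deubiquitinase of the pathway, rose from 10.2 to 23.3. TGF-beta and BMP target genes had 5 rises and 5 falls among 21, with ID3 up from 40.1 to 88.6 and JUNB down from 6.37 to 1.84. Epithelial genes had 1 rise (OCLN, 3.12 to 5.45) and 2 falls (SPINT2, 8.45 to 3.63, and LSR, 20.7 to 13.1) among 14, and mesenchymal genes 3 rises and 2 falls among 18, with TAGLN up from 0.806 to 2.87. ESRP splicing targets, taken as whole genes, had 4 rises and 2 falls among 27, with RAC1 up from 119 to 265. SUMO and ubiquitin partners of Arkadia had 9 rises and 1 fall among 26, with UBE2V2 up from 49.0 to 156 and PIAS4 down from 11.7 to 6.21; their median of 0.30 lay at percentile 87.6.

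Of the other lists with ESRP2 siRNA, p53 targets had 5 rises and 3 falls among 19 (ZMAT3 rose from 0.444 to 2.55), S phase genes 4 and 4 among 28 (SLBP rose from 171 to 401), cholesterol synthesis 6 and 3 among 23 (HMGCS1 rose from 10.8 to 26.2) and oxidative phosphorylation 9 and 6 among 38 (SDHD rose from 61.4 to 205). Hypoxia and glycolysis genes had 6 rises and 5 falls among 28, heat shock genes 2 and 2 among 13, interferon response genes 2 and 2 among 15, immediate early genes 0 and 2 among 17, Wnt targets 1 and 3 among 12 and housekeeping genes 3 and 2 among 15. Neuronal genes had 0 rises and 4 falls among 11, with TUBB3 down from 14.7 to 5.24 beside SYP. Of 24 markers of other cell types, 1 passed the filter on mean FPKM.

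**Figure D2:**
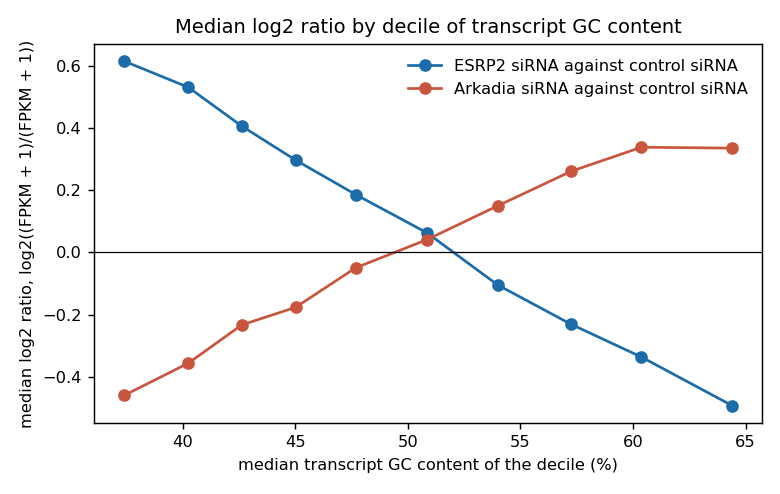
Median log2 ratio of the genes in each decile of transcript GC content (%), for ESRP2 siRNA against control siRNA and Arkadia siRNA against control siRNA; each point is the median of 1176 genes. The ESRP2 siRNA line falls from 0.61 to -0.49 and the Arkadia siRNA line rises from -0.46 to 0.33.

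With Arkadia siRNA, the ribosomal protein gene RPL28 rose 3.87-fold from 759 (360 to 1158) to 2941 (1597 to 4301), RPS19 3.43-fold from 526 to 1802, the RNase P subunit POP7 3.52-fold from 47.1 to 166 and the ubiquitin-like splicing cofactor UBL5 3.77-fold from 173 to 653. The cytokine MIF rose from 1122 to 3947, galactokinase GALK1 from 21.0 to 69.4 and guanylate kinase GUK1 from 216 to 687. Beside RNF111 itself and RPL21, the largest fall, which is described below, C3orf14 fell from 42.2 (18.4 to 65.4) to 7.98 (3.17 to 12.7), the ethanolamine kinase ETNK2 from 23.2 to 5.67 and the glyoxalase GLO1 from 267 to 77.1. UFM1, a ubiquitin-like modifier, fell from 17.1 to 5.09 and the thiol isomerase TMX3 from 7.79 to 1.60.

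TMEM126A rose here as well, by a log2 ratio of 1.84, as did RHEB by 1.69 and FCF1 by 1.57; C1orf53 rose by 2.11 and the non-coding FLJ42875 by 1.84. GOLPH3L fell by 1.63, B4GALT6 by 1.59 and HDHD2 by 1.53. RPL21 stood at an FPKM of 174 with control siRNA and 0.0514 with Arkadia siRNA, EIF5AL1 fell from 20.1 to 4.83 and CDR1 from 34.7 to 10.1. RPL21 and EIF5AL1 have near-identical copies elsewhere in the genome and CDR1 lies opposite a circular antisense RNA, so these 3 values depend on how reads were assigned. The 24 genes named had intervals that did not overlap. For RPL21 this says little, because its interval with Arkadia siRNA was 0 to 0 and did not contain its FPKM of 0.0514.

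In total, 199 genes rose and 266 fell at least 2-fold with Arkadia siRNA, and 23 and 29 of them had intervals that did not overlap. The total of 465 was below that of unchanged libraries drawn from the intervals, 968 (897 to 1041), so those intervals were wider than the scatter between these libraries and the count is not above their noise. The log2 ratio rose with GC content, with a Spearman correlation of 0.57 across genes, from a decile median of -0.46 to 0.33; subtraction left 112 higher and 167 lower genes.

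Ribosomal protein genes as a group were higher with Arkadia siRNA: 23 rose, 7 fell and 47 did neither, with a median log2 ratio of 0.36 at percentile 99.97, and 0.28 at percentile 99.98 after GC subtraction. After length subtraction the median was 0.21 at percentile 98.8. As computed, without subtraction, other genes as short as most of them (up to 1068 nt) with a mean FPKM of at least 100 had a median of 0.25. RPS29 fell from 2907 to 1490. Replication-dependent histones had 2 rises and 11 falls among 23 and a median of -0.34 (percentile 0.260), which GC subtraction moved to -0.63; HIST1H4A and HIST1H4C were listed at 0 with Arkadia siRNA against 4.05 and 2.04 with control siRNA. Neuronal genes that HEK293 cells express had 0 rises and 4 falls among 11, with a median of -0.42 (percentile 1.22, and 0.0300 after GC subtraction). SYP fell from 31.2 to 10.3 and the granin-family gene SCG3 from 2.94 to 0.297, and GAD1 was 9.77 and 13.7. Between Arkadia and ESRP2 siRNA, histones and neuronal genes had direct medians of 0.03 and 0.07 (percentiles 73.0 and 73.1). After GC subtraction these were -0.18 (percentile 2.565) and -0.11 (percentile 29.3). For both lists the shared control library may therefore have stood apart, which cannot be told from an effect of Arkadia siRNA. S phase genes had 0 rises and 5 falls among 28 with a median of -0.19 (percentile 1.16, and 2.69 after GC subtraction), and POLA1 fell from 20.9 to 11.6 and RRM1 from 124 to 72.3.

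Mitosis genes had 1 rise and 5 falls among 30, with a median of -0.22 (percentile 0.740), and KIF11 fell from 30.5 to 17.8 while CDC20 rose from 115 to 210. Splicing regulators had 1 rise and 4 falls among 39 and a median of -0.15 (percentile 1.33), with HNRNPL up from 213 to 369 and QKI down from 13.7 to 6.39. Both lists lay within the central 95% after GC subtraction, at percentiles 18.4 and 26.4. The p53 targets had 2 rises and 4 falls among 19, and their median of -0.23 (percentile 6.72) moved to -0.29 (percentile 0.220) after GC subtraction; AEN fell from 169 to 76.8 and RRM2B from 9.59 to 3.92, and BAX rose from 164 to 358.

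Few members of the TGF-beta lists passed 1.5-fold with Arkadia siRNA, in cells given no TGF-beta. At that size, 1165 of all 11870 genes rose and 1396 fell with Arkadia siRNA. Pathway components had 1 rise and 4 falls among 29: the ligand BMP2 stood at 0.760 with control and 3.97 with Arkadia siRNA with intervals that did not overlap, and SKI, a repressor that Arkadia is known to target for degradation, fell from 19.6 to 7.51 with intervals that overlapped. The target genes had 1 rise (COL1A1, 1.42 to 3.33) and 1 fall (JUNB, 6.37 to 3.81) among 21, and SMAD7 stood at 4.18 and 6.53. Epithelial genes had 0 rises and 0 falls among 14, mesenchymal genes 2 and 2 among 18, ESRP splicing targets 2 and 3 among 27 (FGFR3 rose from 10.4 to 24.1) and SUMO and ubiquitin partners 1 and 6 among 26 (UBE2N fell from 94.0 to 49.1). Their medians lay inside the central 95% of random lists. The list of SUMO and ubiquitin partners contains RNF111 itself, so its 6 falls included the target of the siRNA.

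Of the other lists with Arkadia siRNA, interferon response genes had 0 rises and 0 falls among 15, cholesterol synthesis 3 and 1 among 23, hypoxia and glycolysis 4 and 0 among 28 (NDRG1 rose from 44.2 to 94.1), oxidative phosphorylation 7 and 4 among 38 and stress response genes 3 and 6 among 28 (SDF2L1 fell from 177 to 80.8). Heat shock genes had 0 rises and 1 fall among 13, immediate early genes 0 and 2 among 17, Wnt targets 0 and 1 among 12 and housekeeping genes 3 and 0 among 15, with ACTB up from 933 to 1670.

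**Figure D3:**
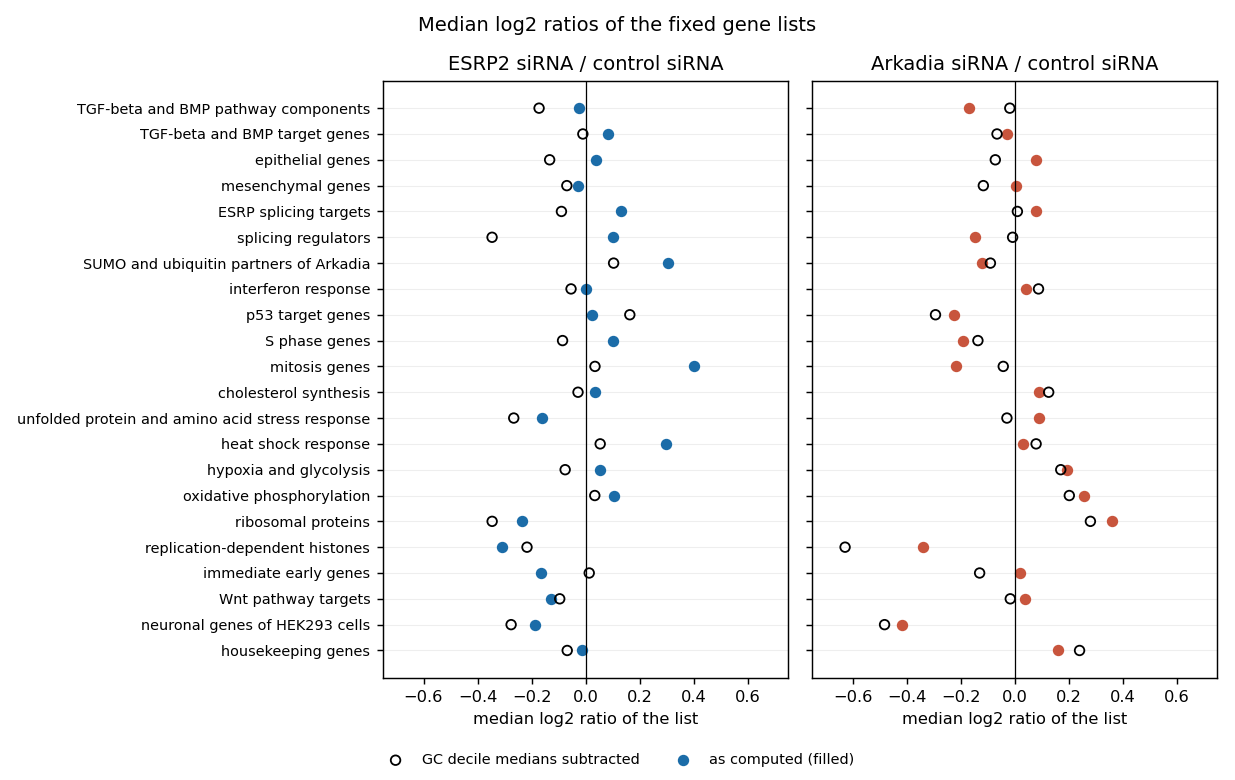
Median log2 ratio of each fixed gene list for ESRP2 siRNA against control siRNA (left) and Arkadia siRNA against control siRNA (right); filled points are the values as computed and open points those after GC decile medians were subtracted. Ribosomal proteins sit at -0.24 on the left and 0.36 on the right, and histones at -0.31 and -0.34.

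In both knockdown libraries, 25 genes rose and 17 fell at least 2-fold against control. The balance was 24 and 18 after rescaling by the median of ratios, but 21 and 25 at the upper quartile and 18 and 25 after length subtraction. TMEM126A, RHEB, FCF1, CAPZB and GALNT7, a glycosyltransferase that went from 4.20 to 20.1 and 12, rose in both, and SYP, SCG3, the neuronal microtubule regulator STMN3 (37.9 to 13.5 and 12.8) and CLEC2L (10.3 to 4.11 and 3.12) fell in both. HBQ1 was 19.3, 5.11 and 7.94 with control, ESRP2 and Arkadia siRNA, CDRT4 0.222, 3.32 and 2.82 and LOC728875 8.01, 2.49 and 2.70. The readthrough genes RPL36A-HNRNPH2, URGCP-MRPS24, ARHGAP19-SLIT1 and MUTED-TXNDC5 also met the rule, with values that share reads with their component genes and are uncertain. Such genes are equally those in which the control library stood apart from the other 2.

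At 2-fold, independent lists would share 10.8 genes upward and 6.43 downward. At 1.5-fold, 177 genes rose and 101 fell in both, fewer than the 232 and 159 of independent lists, so the excess depended on the size chosen. Unchanged libraries that share 1 control, drawn from the intervals, shared 240 and 70 at 2-fold (medians). The control could not be split, so part of any excess over independent lists may come from it. Across genes the log2 ratios of both comparisons correlated with Pearson's r of -0.21 and a covariance of -0.0608, against 0.50 and 0.196 in the simulated sets. After GC subtraction r was 0.16 and the covariance 0.0302, and 25 genes rose and 21 fell in both, where independent lists would share 2.61 and 2.60. At 1.5-fold these were 198 and 129 genes, against 66.5 and 62.1. No unchanged libraries sharing the control were drawn after GC subtraction, so the part that the control adds to this agreement is not known. Conversely, as computed, 28 genes moved at least 2-fold in opposite directions, 25 up with ESRP2 siRNA and 3 up with Arkadia siRNA. Independent lists would give 14.5 and 4.81. After GC subtraction 7 genes did so, against 5.63 for independent lists.

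The direct comparison of both knockdowns differed most. With Arkadia siRNA, POP7 was 6.51-fold above its ESRP2 siRNA level (166 against 25.5), EMP3, a membrane protein, 7.54-fold (30.4 against 4.03), the mitochondrial ribosomal protein MRPL54 6.59-fold, RPS28 5.65-fold and METRNL 9.56-fold (10.1 against 1.05). RG9MTD1, a mitochondrial RNase P subunit, was 26.8 with Arkadia siRNA and 211 with ESRP2 siRNA, COMMD9 9.74 and 74.7, the signal peptidase subunit SPCS3 8.69 and 66.8 and the adaptor subunit AP3S2 7.34 and 64.5. RPL21 was again the largest fall, with the caveat above.

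In all, 1056 genes were higher and 1837 lower with Arkadia than with ESRP2 siRNA, and 221 and 528 of them had intervals that did not overlap; the total of 2893 exceeded the 904 to 1047 of unchanged libraries. The median of ratios gave 1446 higher and 1369 lower genes and the upper quartile 1464 and 1354. The log2 ratio rose with GC content with a Spearman correlation of 0.76 across genes, from a decile median of -1.08 to 0.80, and 380 higher and 521 lower genes were left after subtraction. Ribosomal proteins (37 higher, 7 lower, 33 neither, median 0.48, percentile 99.98) and mitosis genes (2 higher, 14 lower among 30, median -0.51, percentile 1.79) lay outside the central 95% of random lists. After GC subtraction ribosomal proteins stayed outside (median 0.57), whereas mitosis genes had 0 higher and 3 lower, a median of 0.0776 and a percentile of 80.4.

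Isoform usage addressed the splicing function of ESRP2. Of 19 ESRP splicing targets with at least 2 isoforms and enough expression, 9 changed usage by 0.25 or more with ESRP2 siRNA and 6 with Arkadia siRNA. ENAH, an actin regulator, moved toward the isoform NM_018212, which is shorter by 63 nt, from 70.7% with control siRNA to 96.0% and 91.2%. The cell polarity gene SCRIB moved toward NM_015356, shorter by 75 nt, from 69.3% to 100% and 94.3%, and ARHGEF11 away from NM_198236, longer by 120 nt, from 71.7% to 21.5% and 46.9%. The usage changes of these 3 genes with Arkadia siRNA were 0.205 for ENAH, 0.24997 for SCRIB and 0.248 for ARHGEF11, and none of them passed the threshold.

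CTNND1, which encodes p120 catenin, fell from 82.8% to 47.7% and 53.2% for NM_001085460, TCF7L2 from 34.3% to 15.3% and 9.64% for NM_030756, and GIT2 changed by 0.356 and 0.277 in usage. These 3 targets passed in both knockdowns, but in GIT2 different isoforms moved. Its isoform NM_139201 went from 37.5% with control siRNA to 8.72% with ESRP2 siRNA and 38.0% with Arkadia siRNA. For NM_014776 the shares were 32.0%, 30.2% and 4.33%. FGFR1 moved from 29.7% to 58.6% and 43.9% for NM_001174066 and DNM2 from 26.6% to 51.3% and 27.0% for NM_004945. FGFR2 (0.440), PLEKHA1 (0.324) and ITGA6 (0.266) passed with Arkadia siRNA and had changes of 0.204, 0.0851 and 0.179 with ESRP2 siRNA. EXOC7 (0.215 and 0.0714), MAP3K7 (0.221 and 0.0751), NUMB (0.191 and 0.138), LSR (0.131 and 0.227), FGFR3 (0.106 and 0.166) and RAC1 (0.0157 and 0.0200) did not pass with either. The leading isoform went the same way in both knockdowns for 12 of the 19 targets (63.2%), against 58.4% of all 3413 genes compared, which share the control library too.

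**Figure D4:**
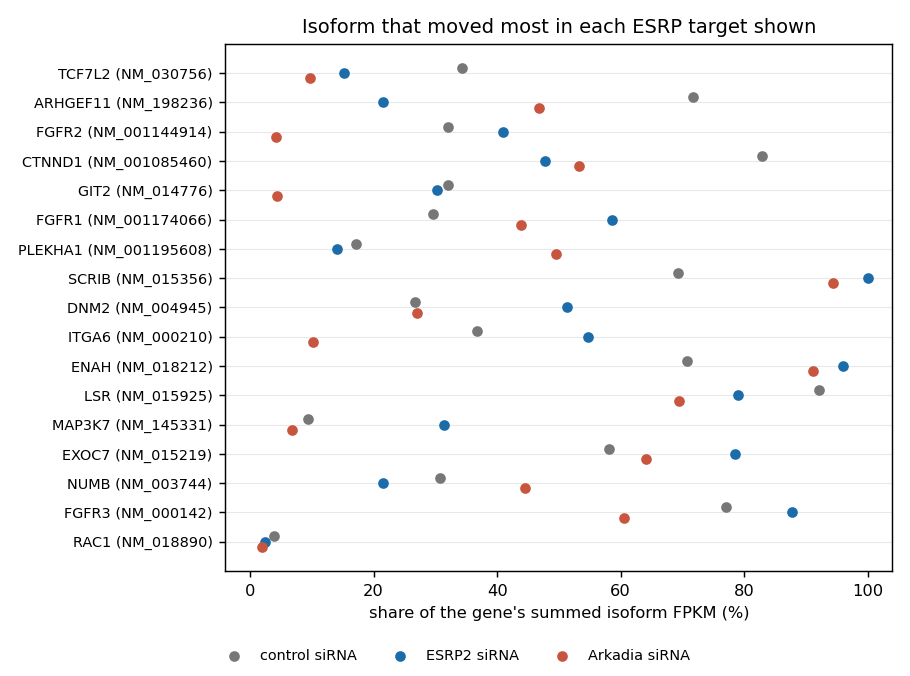
Share (%) of the isoform that moved most in each of 17 ESRP splicing targets, in the control, ESRP2 and Arkadia siRNA libraries, with 1 point per library. ENAH NM_018212 lies at 70.7%, 96.0% and 91.2%, and ARHGEF11 NM_198236 at 71.7%, 21.5% and 46.9%.

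The median usage change of the targets was 0.25 with ESRP2 siRNA (percentile 99.5 of random lists matched on summed FPKM) and 0.22 with Arkadia siRNA (percentile 99.6). Matched also on isoform number, these were percentiles 98.1 and 97.3, the latter inside the central 95%, and 5.52 and 4.82 targets would pass by that matching. For most target isoforms the authors' intervals overlapped between libraries.

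Among all 3413 genes, 683 changed usage with ESRP2 siRNA, 582 with Arkadia siRNA and 275 with both. The 8 largest changes with ESRP2 siRNA were in CRBN, C20orf96, VARS2, PHF1, RGMA, CUX1, MAN2C1 and BBC3. CRBN went from 99.96% to 0.223% of NM_016302, which differs from the other isoform by 3 nt, and CUX1 from 67.4% to 0% of NM_001913. With Arkadia siRNA the 8 largest included FANCL, PACSIN3, PHF1, TGFBRAP1, SLC25A14, MYADM and PARN; FANCL went from 0.00533% to 99.8% of NM_001114636, and PHF1 from 97.8% to 0.107% and 0.130% of NM_024165 with ESRP2 and Arkadia siRNA. Unchanged libraries drawn from the intervals gave 484 and 488 genes and 215 in both (182 to 249), and independent lists would share 116. Each isoform was drawn independently of the others of its gene, which real estimates may not be, so the drawn numbers are an approximate reference. Of the 275 genes, 192 had their leading isoform move the same way in both. With at least 1 isoform whose intervals did not overlap, 244, 171 and 51 genes were left.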

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

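The tests of GC content, transcript length, pseudogenes and expression level below were all chosen after the patterns had been seen. The covariance beside simulated libraries that share the control was planned for the genes changed in both knockdowns. Its use on genes that moved in opposite directions was chosen later. What each explanation predicted was set down before its result was computed. Bootstrap intervals below resample genes of the same libraries, so they do not measure the spread between libraries or siRNAs.

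In opposite directions, at least 2-fold each, moved 28 genes: 25, such as SPCS3, COMMD9, TIPIN and CALM2, rose with ESRP2 siRNA and fell with Arkadia siRNA, and COL6A2, MRPL54 and TM7SF2 did the reverse. Independent lists would give 14.5 genes up with ESRP2 siRNA and down with Arkadia siRNA, and 4.81 the reverse. Over all genes, 7 moved in opposite directions after GC subtraction, against 5.63 for independent lists. The 28 genes stood out because the libraries went opposite ways, but the difference itself was not tested, as each group has 1 library. After subtraction of GC decile medians a share of 0.0741 of those with a GC value still passed (95% bootstrap interval 0 to 0.190), and the number of genes 2-fold apart between both knockdown libraries dropped to 0.314 of its former size (0.295 to 0.333), so a trend with transcript GC content may account for most of this pattern. Length subtraction left a share of 0.571 of the opposite genes (0.385 to 0.75), which leaves length open for them, but 0.947 of the 2-fold genes (0.925 to 0.968). Noise of the shared control was predicted to give a covariance of 0 or above. The covariance was -0.0608 (-0.0669 to -0.0549) as computed and 0.0302 after GC subtraction. Such noise moves both ratios the same way and could not give opposite changes, so this test decides nothing about them. Whether the GC trend came from library preparation or sequencing, or from a change of GC-rich and GC-poor transcripts after the siRNAs, stays open with 1 library per siRNA.

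Ribosomal protein genes were higher with Arkadia than with ESRP2 siRNA, by a median log2 ratio of 0.48. After GC subtraction the list lay at percentile 100 of matched random lists with a median of 0.57, and after length subtraction at percentile 99.755 with a median of 0.35. This argues against a trend with GC content, or with the length of the longest isoform, as the whole cause when each is taken alone. The longest isoform need not be the one expressed, and it was 4879 nt for RPL27A and 4401 nt for RPL28. GC content and length were not subtracted together, so their joint trend stays open. The 38 members with the fewest annotated pseudogenes (at most 8 each) had a median of 0.75, and after GC subtraction 0.57 against 0.54 for the other 39, both times at percentile 100 of random lists matched on FPKM, which argues against reads shared with pseudogenes as the whole cause. Other genes as short as most ribosomal protein genes (up to 1068 nt) had a median of 0.21 (740 genes), and 0.14 among the 230 with a mean FPKM of at least 100. A response of ribosomal protein transcripts to the siRNAs is a hypothesis that these data leave open, as are other differences in preparation between the libraries, which were not tested.

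Isoform usage changed in both knockdowns in 275 genes, where unchanged libraries sharing 1 control, with each isoform drawn independently, gave 215 (182 to 249). Such genes made up 13.3% of the genes with the lowest summed FPKM (151 of 1137) and 3.25% of those with the highest (37 of 1138), a ratio of 0.245 (0.161 to 0.341). Noise of isoform estimates at low expression is therefore a candidate explanation for a large part of them. A shared effect of both knockdowns on splicing stays open for the remainder, and the control library cannot be split to test it.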

How the results depend on the processing

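Of 74 recomputed values that answer a comparison, 48 stayed the same and 26 did not. Staying the same meant within 1.5 times the reported count. For the log2 ratios of the siRNA targets it meant a move of less than the SD derived from the authors' intervals. The GC, length and isoform-number alternatives were chosen after the data were seen. With a pseudocount of 0.1 the genes past 2-fold were 1505 (ESRP2 siRNA), 861 (Arkadia siRNA) and 103 in both, and the log2 ratio of RNF111 was -2.37; with 5 they were 389, 155, 1398 (direct) and 16, and RNF111 was -0.89, which follows from the construction of the scale. Requiring intervals that did not overlap left 148, 52, 749 and 5 genes. GC subtraction left 457, 279 and 901, and reversed the median of mitosis genes (0.0776, from -0.51) and CHORDC1 (0.30, from -0.78) in the direct comparison; the cause was not tested. Lists outside the central 95% in the knockdown comparisons numbered 6 with a mean FPKM filter of 5 and 6 after length subtraction, against 10 as reported; the cause was not tested. For isoforms, a summed FPKM of at least 2 gave 913 (Arkadia siRNA) and 443 (both), at least 20 gave 204, 175 and 61, where fewer genes entered (4400 and 1515 against 3413), and isoforms with intervals that did not overlap gave 244, 171 and 51.

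Rescaling, no filter on mean FPKM, all statuses and summed isoform FPKM kept every such total within 1.5 times, where computed, but rescaling turned the 647 rises and 287 falls with ESRP2 siRNA into 417 and 448 (median of ratios) or 361 and 522 (upper quartile). Of 549 recomputed list medians 519 and of 3207 recomputed ratios of named genes 3011 kept their side of the threshold or range. The shallower Arkadia siRNA library limits low genes most. No paired analysis was possible because the labels give 1 library per group, and for the same reason no library could be left out and no other split of the libraries was possible.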

Other observations

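Genes that moved the same way in both knockdowns beyond the GC trends were looked for after the data were seen, by subtracting the GC decile medians. Besides genes named above, LDHB, the heart-type lactate dehydrogenase subunit, was 451 with control, 1694 with ESRP2 and 965 with Arkadia siRNA, the sphingosine phosphate phosphatase SGPP1 2.74, 15.0 and 5.98, and the prenyltransferase subunit PGGT1B 1.96, 10.3 and 5.16. Lower in both were the glutathione transferase GSTP1 with 711, 236 and 404, KCTD12 with 73.3, 33.6 and 28.3, the CaM kinase inhibitor CAMK2N2 with 5.74, 1.16 and 2.57 and CNRIP1 with 8.69, 3.15 and 3.89. Of the 24 named genes per knockdown, 19 with ESRP2 siRNA and 22 with Arkadia siRNA were also among the largest changes after subtraction.

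In the direct comparison 4 further lists lay outside the central 95% only after GC subtraction, or after GC and length subtraction in the case of stress response genes. Oxidative phosphorylation genes had 10 members higher and 7 lower with Arkadia siRNA after GC subtraction, with a median of 0.29 at percentile 99.3, against 9 and 9 with a median of 0.18 at percentile 82.1 as computed and percentile 69.7 after length subtraction. The stress response genes had 5 higher and 1 lower with a median of 0.28 at percentile 99.3, against 11 and 5 with a median of 0.28 at percentile 95.1 as computed and percentile 98.0 after length subtraction. The p53 targets had 2 higher and 8 lower with a median of -0.45 at percentile 0.140, against 4 and 7 with a median of -0.09 at percentile 57.2 as computed and percentile 46.0 after length subtraction. Housekeeping genes moved as well, from a median of 0.21 at percentile 76.9 to 0.45 at percentile 99.0, with 5 higher and 2 lower among 15, so these lists depend on the subtraction.

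Isoform pairs of nearly the same length were common among the largest usage changes. Of 35 genes whose usage changed by 0.75 or more in either knockdown, 11 (31.4%) had leading isoforms within 10 nt of each other, against 184 of 2423 genes (7.59%) past the threshold in neither; CRBN, C20orf96, PACSIN3, TGFBRAP1 and VARS2 are of this kind, with 3 or 4 nt between isoforms. Of the 3413 genes tested, 73 had transcripts listed at several loci, and in 33 of them all isoforms were copies of 1 transcript; summing the copies left 683 genes with ESRP2 siRNA and 582 with Arkadia siRNA, as before. For genes past 0.25 with ESRP2 siRNA the share was 8.49%, and for the ESRP targets FGFR3 and DNM2 the leading isoforms differed by 6 and 9 nt, against 63 nt for ENAH, 75 nt for SCRIB and 120 nt for ARHGEF11.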
